A study of Caenorhabditis elegans with 6 samples.

How the data were processed

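The series measured where UNC-62, a TALE-family homeodomain transcription factor, bound the genome of Caenorhabditis elegans at the fourth larval stage (L4), by chromatin immunoprecipitation followed by sequencing (ChIP-seq). Whole worms carried a transgene, wgIs600, with unc-62 joined to a TY1, EGFP and FLAG tag and unc-119 as its marker, and the labels give the target as the EGFP-tagged protein. There was 1 condition, with 6 libraries that the labels number as biological replicates. The labels give the worm source of replicates 1 and 2 as CGC, with a fragment size range of 150 to 350, and that of replicates 3 to 6 as Michael Snyder, with sonication. The worm source and the fragmentation entry therefore change together and cannot be told apart.

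The files were lists of peaks, each with a position, a summit and values from the peak caller. Per the file lists deposited with the libraries, the authors called peaks in each library, and also on pooled alignments of 4 libraries, replicates 1, 2, 3 and 4. The final list, which the deposited files call the optimal list at a threshold of the irreproducible discovery rate (IDR), was derived from the pooled list and the lists of 5 libraries, replicates 2 to 6. All 2761 optimal peaks were in the pooled list of 15864 peaks. Of that list, 2761 peaks had a signal at or above the lowest optimal signal, 44.7. The optimal list was thus the top of the pooled list by signal, and a peak in it need not recur in single libraries. All 6 library lists were derived with 1 shared control file. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. Column 7 of each deposited list holds the peak's signal value, a score on the authors' peak caller's own scale, which moves with depth, and it was used here only to rank and describe peaks within a list. The deposited −log10 q values of each peak have a ceiling in each list, from 2.18 in replicate 5 to 4.16 in replicate 4, and were only described. The library lists were long lists meant as input to IDR, with 30000 peaks in each library except replicate 3, which had 28902, so they hold background as well as bound sites. The number of reads per library is unknown here, so no value could be scaled to depth, and the intervals given cover counting error over peaks or genes only. No control track was analysed here.

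The main lists were on ce11, whose chromosome sequences are those of WBcel235, and positions are given 1-based on that build. Lists on ce10 served as alternatives, and no position was converted between builds. Peaks on the mitochondrial genome were left out of all comparisons. Gene annotation came from Ensembl release 115, with 19973 protein-coding genes on the nuclear chromosomes. Calculations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and figures used Matplotlib 3.10.9.

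Equal numbers of peaks were compared between libraries: the 2761 nuclear peaks of highest signal in each, the size of the optimal list, called top-ranked peaks from here on. A pair of peaks matched when their summits lay within 100 bp. A promoter was 1000 bp upstream to 200 bp downstream of an annotated protein-coding transcription start site (TSS), and a gene counted as bound when an optimal summit lay in its promoter. Promoter shares were compared with 10000 random placements on the same chromosomes (one-sided). The X chromosome's share of promoter peaks was compared with 10000 draws of promoter windows (two-sided). Overlap within and between worm-source labels was compared by an exact permutation over 15 splits (two-sided). Signal values were compared by Spearman correlation across matched optimal peaks, which are not independent replicates. Gene lists were compared with all other protein-coding genes by Fisher's exact test (two-sided) with Benjamini-Hochberg adjustment over 21 lists, and again with 10000 random lists matched on upstream intergenic length in 10 bins. Neighbouring genes can share a peak, so the genes of a list are not independent. Sequence motifs were counted, on either strand, within 50 bp of each summit and in flanks 250 to 350 bp away, and tested by 10000 sign flips over peaks (one-sided). For these ratios a flank count of 0 was set to 1 window. All hexamers were also ranked by their ratio, with 1 added to the flank count. The smallest p these permutations can give is 0.0001 one-sided and 0.0002 two-sided. Shares carry exact Clopper-Pearson 95% intervals. Nothing in the labels says more about how the replicate worms were grown, so tests over libraries measure the spread between these samples.

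The gene lists, fixed before the data were examined, were Hox genes, TALE homeobox genes, vitellogenins, intestine, hypodermis and seam, cuticle collagens, molting, body wall muscle, pharynx, pan-neuronal, neuronal identity factors, vulva, Wnt pathway, axon and cell guidance, heterochronic, insulin signalling, germline, major sperm proteins, ribosomal proteins, proteasome and histones. Of the heterochronic names 5, all microRNA genes, did not match the annotation's names, and 10 protein-coding genes were tested. Genes were named by a rule fixed at the same time. It took the genes of the 20 optimal peaks of highest signal (the nearest protein-coding TSS where no promoter held the summit), all Hox and TALE genes, and unc-62 and unc-119. From each other list it took at most 4 members with an optimal promoter peak, by the number of libraries matching and then by signal. The motifs TGACAG, TGAKTGACAG, TGATTNAT, WGATAR and GAGAG were fixed then too; ACGCAG and CTTATC were chosen after seeing the hexamer ranks.

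The functions were tested on simulated data. Of 2 simulated lists made to share 40.0% of 2761 peaks, 40.4% was found. TGACAG planted in windows gave a ratio of 3.58 and rank 1, and random positions gave 0.966. In the first simulation of the list test, with lists of 20 genes bound at 3 times the background and adjusted with 90 unchanged lists, 0 of 10 changed lists and 0 of 90 unchanged lists were called. Simulations with the real number of lists were then added. At 3 times the background 30.5% of changed lists were called, and at 6 times 98%, with 0.909% and 2.27% of unchanged lists. A list of about 20 genes that did not pass may therefore still be bound several times more often than other genes.

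Alternatives planned beforehand were the ce10 lists, merged peaks, promoters of 500 bp upstream to 100 bp downstream or 2000 bp upstream to 200 bp downstream, and the 1380 optimal peaks of highest signal. Others were an overlap of 1 bp or a reciprocal overlap of 50%, the top 1000 or 5522 peaks or whole lists, replicates 3 to 6 alone, assignment to the nearest TSS only, matched random lists, each library's own top-ranked peaks, motif windows of 25 or 100 bp each side, and random promoter windows. Assignment to the nearest TSS used every peak at any distance, so a gene counted as bound there without a promoter peak. Replicates 1 to 4 alone were added after seeing the data.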

Results

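UNC-62 binding was mapped by ChIP-seq against an EGFP-tagged protein in whole L4 larvae, in 6 libraries of 1 condition. The question the design puts is where the protein bound and how far the libraries gave the same sites. Each library list held 28902 or 30000 peaks, and the number of reads behind them is unknown. The highest nuclear signal value was 57.8, 64.7, 234, 224, 53.4 and 32.4 in replicates 1 to 6. Peaks with a q value of at most 0.01 numbered 1593, 1902, 13335, 12946, 271 and 666 in the same order, values that also move with depth.

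The strongest UNC-62 sites lay both in and away from annotated promoters, and unc-62 itself was among their nearest genes. The optimal list held 2761 nuclear peaks, with a median width of 360 bp. The highest signal, 587, belonged to an intergenic peak on chromosome I (13337172 to 13337443), 1172 bp upstream of casc-3. The next, 387, was an intergenic peak on chromosome II (12518905 to 12519165), 165 bp upstream of srh-70, a chemoreceptor-family gene, and 957 bp upstream of the homeobox gene ceh-99. Signal 361 followed, at a peak on chromosome V (4491386 to 4491620), 5954 bp upstream of the nearest unc-62 TSS. Among the 20 strongest peaks, summits fell in the promoters of nspc-17, tasp-1 and K01G5.10, H41C03.3, ttr-45, the histone gene his-37, cdc-48.1, which encodes an AAA-ATPase of protein turnover, rpl-3, which encodes a protein of the large ribosomal subunit, and vrp-1 with Y54G2A.28. The others of the 20 had their nearest TSS at M106.2, Y111B2A.12, fbxl-5, pigx-1, jmjd-3.1, fkh-7, asp-13, W02H3.3 and F17C11.22, between 1357 and 8410 bp away.

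These strong sites did not rank alike in every library. The casc-3 peak ranked 41, 61, 1, 1, 3 and 10 in replicates 1 to 6. The tasp-1 peak ranked 15, 1, 64, 76, 16 and 5. The peak near asp-13 ranked 11 and 2 in replicates 3 and 4 and 145 and 76 in replicates 5 and 6, and had no match in the lists of replicates 1 and 2. The peak near jmjd-3.1, a histone demethylase gene, ranked 4 and 11 in replicates 3 and 4, 35 and 163 in replicates 5 and 6, and 6938 in replicate 2, with no match in replicate 1.

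UNC-62 peaks were concentrated upstream of genes and were rare in coding sequence. Of the optimal summits, 48.6% (95% interval 46.7% to 50.5%) lay in promoters, against 25.8% of random positions, a 1.88-fold excess (permutation p = 0.0001, the smallest possible). They covered 1495 genes, 7.49% of protein-coding genes, and 239 peaks lay in promoters of more than 1 gene. By annotation at the summit, 57.4% were intergenic, 24.5% intronic, 4.06% in 5' UTRs and 3.91% in coding exons, where random positions gave 35.3%, 32.3%, 1.46% and 24.2%. The promoter share of top-ranked peaks was 39.2% ± 9.33 (SD, n = 6 libraries) and passed the random share in 6 of 6. By library it was 34.7%, 35.0%, 50.6%, 51.6%, 32.9% and 30.6%. Coding exons held 21.5%, 22.2%, 4.42%, 4.56%, 19.5% and 26.2% of the same peaks.

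The X chromosome carried more optimal peaks than its promoters account for. It held 712 optimal peaks, 25.8% (24.2% to 27.5%), or 40.2 per Mb, against 21.3 to 28.7 per Mb on the autosomes. Of promoter peaks, 23.9% were on X, where 13.9% of promoter windows lie (permutation p = 0.0002, the smallest possible). The X share of top-ranked peaks was 23.7% ± 1.82 (SD, n = 6), and in every library the promoter peaks exceeded the window share. It was 26.5% and 24.9% in replicates 3 and 4, and 22.9% and 22.6% in replicates 5 and 6, which matched the optimal list least. X holds 17.7% of the nuclear genome. With no control track analysed, an X excess of background was not set apart from one of binding. Among the X peaks were those at nspc-17 (signal 322), near pigx-1 (311) and at vit-2 (178).

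Few sites were found in all 6 libraries, and those included unc-62 and ribosomal protein promoters. Of the optimal peaks, 58 (2.10%, 1.60% to 2.71%) matched a top-ranked peak in all 6, among them those at casc-3, tasp-1, his-37, rpl-3 and the 5' UTR of unc-62. A further 144 (5.22%) matched none, and the rest matched at least 1 library. Of randomly placed summits, 2.67% matched at least 1 library. The random share for a match in all 6 was not computed. The share of optimal peaks matched was 27.9%, 31.4%, 65.7%, 65.2%, 15.5% and 12.4% in replicates 1 to 6. The optimal list was called on the pooled alignments of replicates 1 to 4, so its match to those libraries is not independent. Among replicates 1 to 4 alone, 8.48% of optimal peaks matched in each.

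Pairs of libraries shared 15.1% ± 12.8 of top-ranked peaks (SD over 15 pairs, which share libraries), against 0.568% under random placement and 0.788% when the promoter share was kept. The highest pair was replicates 3 and 4, with 57.4%, and the lowest replicates 5 and 6, with 6.99%. Replicates 1 and 2 shared 19.4%. Spearman's rho of signal across optimal peaks matched in both libraries averaged 0.25 ± 0.14 (SD, 15 pairs), from 0.088 for replicates 1 and 4 to 0.60 for replicates 3 and 4. Pairs within a worm-source label shared 17.3% and pairs between labels 13.1%, a difference of 4.23 percentage points that did not pass (exact permutation p = 0.667). With 15 splits the smallest possible exact p is 0.0667, so this comparison could not reach 0.05. The difference rests on the pair of replicates 3 and 4: it was 0.0905 points without replicate 3 and 0.0513 without replicate 4, alternatives chosen after seeing the data.

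**Figure D1:**
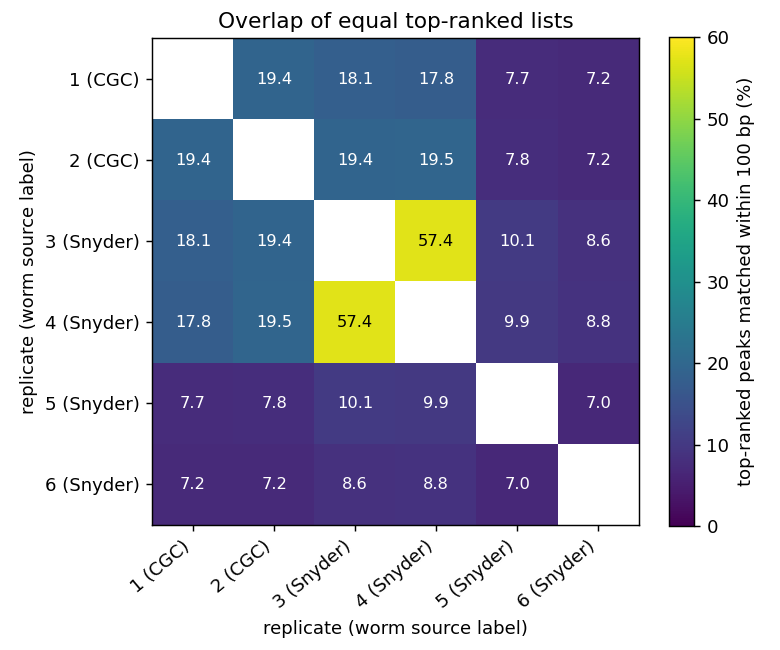
Share (%) of the 2761 top-ranked peaks of each library with a summit within 100 bp of one in another library, for all 15 pairs; rows and columns are replicates with their worm source label. Replicates 3 and 4 share 57.4%, and the lowest pair shares 6.99%.

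Ribosomal protein genes, vitellogenin genes, intestinal genes and TALE homeobox genes were bound more often than other genes. Of 76 ribosomal protein genes 30 were bound (39.5%, 28.4% to 51.4%), 5.36 times the share of other genes (Fisher's exact test, adjusted p = 1.17e-13). With each peak given to the nearest TSS at any distance, the ratio was 2.25 (exact test, adjusted p = 0.00422). The share was above that of other genes in 6 of 6 libraries, with 19, 25, 25, 26, 13 and 10 genes bound in replicates 1 to 6. The ribosomal list passed in replicates 5 and 6 too, where only 15.5% and 12.4% of optimal peaks matched. No control track was analysed here, so peaks called at these promoters without UNC-62 could not be set apart. The peaks at rpl-3 (signal 259), rpl-15 (212), rpl-35 (184) and rpl-20 (171) matched in all 6 libraries. Of the 6 vitellogenins, the yolk proteins made in the adult intestine, 5 were bound (83.3%, 35.9% to 99.6%), 11.2 times the share of other genes (exact test, adjusted p = 0.000138). Their summits lay at most 185 bp upstream of the TSS, with signals of 191 at vit-6, 178 at vit-2, 83.5 at vit-5 and 80.0 at vit-1. The number of vitellogenins bound was 0, 0, 6, 6, 1 and 0 in replicates 1 to 6, and the list passed in replicates 3 and 4 alone.

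Intestinal genes were bound in 7 of 15 cases (46.7%, 21.3% to 73.4%), 6.26 times the share of other genes (exact test, adjusted p = 0.000342). They included act-5, the actin of intestinal microvilli (signal 180), elt-2, the GATA factor of the intestine (79.0), the protease gene asp-1 (51.6) and the sodium-proton exchanger gene nhx-2 (58.5). The peaks at act-5, elt-2 and asp-1 each had a top-ranked match in 3 libraries, and that at nhx-2 in replicate 5 alone, at rank 2724. The libraries gave 2, 1, 4, 8, 3 and 3 of 15. The list passed with the top-ranked peaks of replicate 4 only; in the other libraries the ratio was 1.27 to 4.63 and the exact tests gave adjusted p from 0.0948 to 0.934, and among the 1380 optimal peaks of highest signal 0.273. Random lists of the same upstream lengths left all 4 calls standing, with adjusted p between 0.0021 and 0.021.

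Of the 4 TALE genes 3 were bound (75%, 19.4% to 99.4%), 10.04 times the share of other genes (exact test, adjusted p = 0.0083). They were unc-62, ceh-20, which encodes a PBX-type partner of Hox proteins (signal 215, chromosome III 6979122 to 6979213, 738 bp upstream), and ceh-60 (106, chromosome X 6530650 to 6531009, 684 bp upstream). The closest optimal summit to ceh-40 was 32362 bp away. The libraries gave 2, 2, 3, 3, 1 and 2 of the 4. The call rests on 3 genes, of which 1 is unc-62, which the transgene also carries, and the list was not tested without it. The call ended with the promoter of 500 bp upstream (exact test, adjusted p = 0.424). With each library's own top-ranked peaks it passed in replicates 3 and 4 and not in replicates 1, 2, 5 and 6 (exact tests, adjusted p from 0.0646 to 0.533). The ratio was 9.54, 9.55, 9.94, 9.77, 5.23 and 11.6 in replicates 1 to 6, near the optimal list's in each library but replicate 5. In replicates 1, 2 and 6 it did so with 2 genes rather than 3. There the share of all protein-coding genes bound was lower too, 5.25%, 5.25% and 4.34% against 7.49%. Of the 6 Hox genes, lin-39 (signal 107, chromosome III 7534663 to 7535022) and ceh-13 (94.95, 7554888 to 7555247) were bound, and both peaks matched in 5 libraries. This list did not pass (exact test, adjusted p = 0.18). The closest summits to mab-5, egl-5, php-3 and nob-1 lay 24669, 40327, 17106 and 10346 bp away.

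The other 16 lists did not pass. Wnt pathway genes were bound in 5 of 27 cases, with peaks at mig-5 (signal 133, matched in 5 libraries), pry-1, dsh-2 and lit-1 (exact test, adjusted p = 0.166). Insulin signalling genes gave 3 of 12, akt-2, ins-7 and sgk-1 (exact test, adjusted p = 0.166). Cuticle collagens gave 6 of 173, 3.47% against 7.52% of other genes (exact test, adjusted p = 0.166), among them col-74, col-38, col-63 and col-185. Pan-neuronal genes gave 3 of 17, snb-1, unc-11 and rgef-1, and pharynx genes 2 of 10, pha-2 and pha-4. Heterochronic genes gave 2 of 10, lin-28 and alg-1, and axon and cell guidance genes 2 of 12, unc-40 and mig-10. Body wall muscle genes gave 2 of 23, unc-112 and unc-60, and proteasome genes 4 of 33, rpn-3, rpn-11, rpn-5 and rpn-9. Single genes were bound among hypodermis and seam genes (elt-3, of 16), neuronal identity factors (mec-3, of 18), vulva genes (egl-17, of 18), germline genes (nos-3, of 23) and histones (his-37, of 50). No optimal promoter peak was found at 19 molting genes or 31 major sperm protein genes, which allows a share of up to 17.6% and 11.2%. The adjusted p of these 13 lists ranged from 0.291 to 1 (exact tests). The number of lists bound more often was 9 when each peak was given to the nearest TSS at any distance, without the promoter window. It was 2, 4, 3, 4, 2 and 1 with the top-ranked peaks of replicates 1 to 6.

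**Figure D2:**
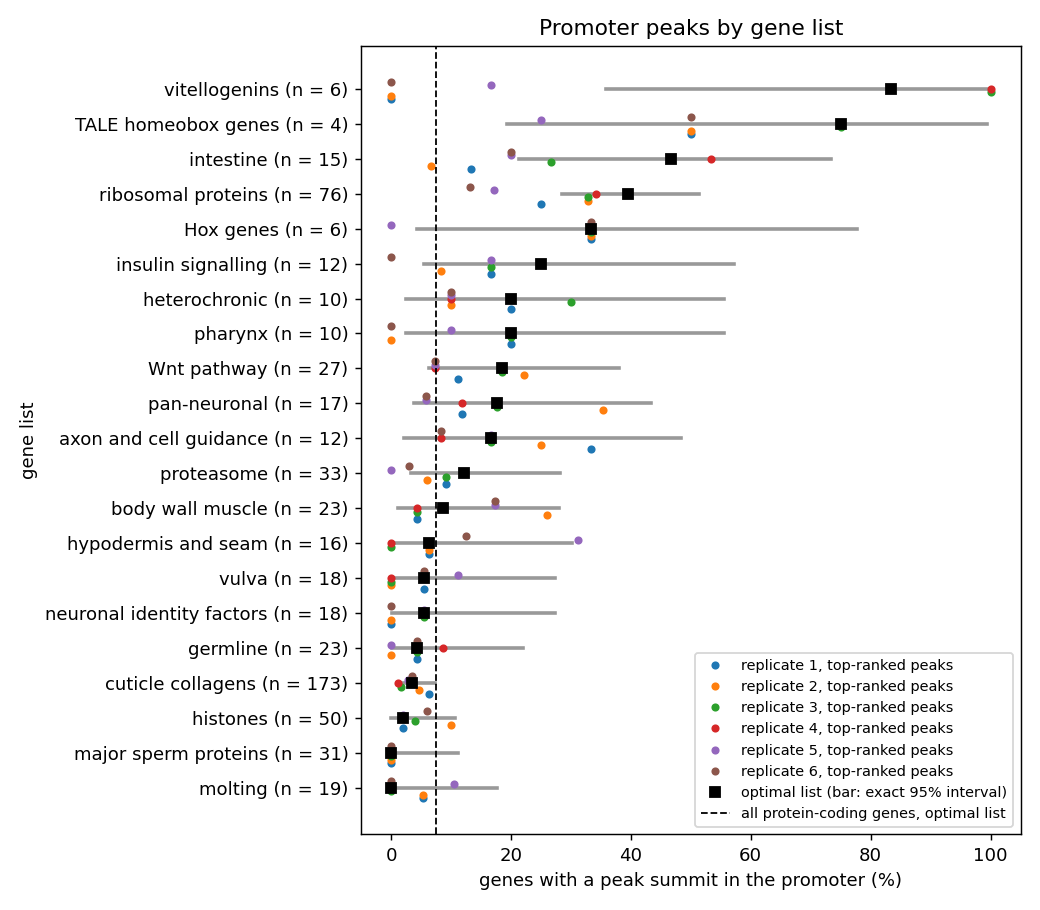
Share (%) of each list's genes with a peak summit in the promoter; black squares are the optimal list with its exact 95% interval, coloured points are the top-ranked peaks of each replicate, and the dashed line is all protein-coding genes (7.49%). Vitellogenins reach 6 of 6 genes in replicates 3 and 4, while ribosomal protein genes lie above the line in every library.

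The unc-62 locus carried 15 optimal peaks within 15 kb of the gene (chromosome V, 4497461 to 4511449, plus strand). The strongest were the upstream intergenic peak of signal 361 and peaks in 5' UTRs of unc-62 isoforms at 4499663 (238), 4508011 (196) and 4508290 (170). Whole library lists gave 40, 37, 40, 42, 35 and 36 peaks in that window in replicates 1 to 6, where equally long windows at other genes averaged 12.6 to 13.4. At unc-119 (chromosome III, 10902641 to 10908935), the marker gene, no optimal peak lay within 15 kb, and the libraries gave 9, 10, 2, 8, 8 and 8 peaks. Extra copies of sequence in the strain can raise the signal at the genes the transgene carries.

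**Figure D3:**
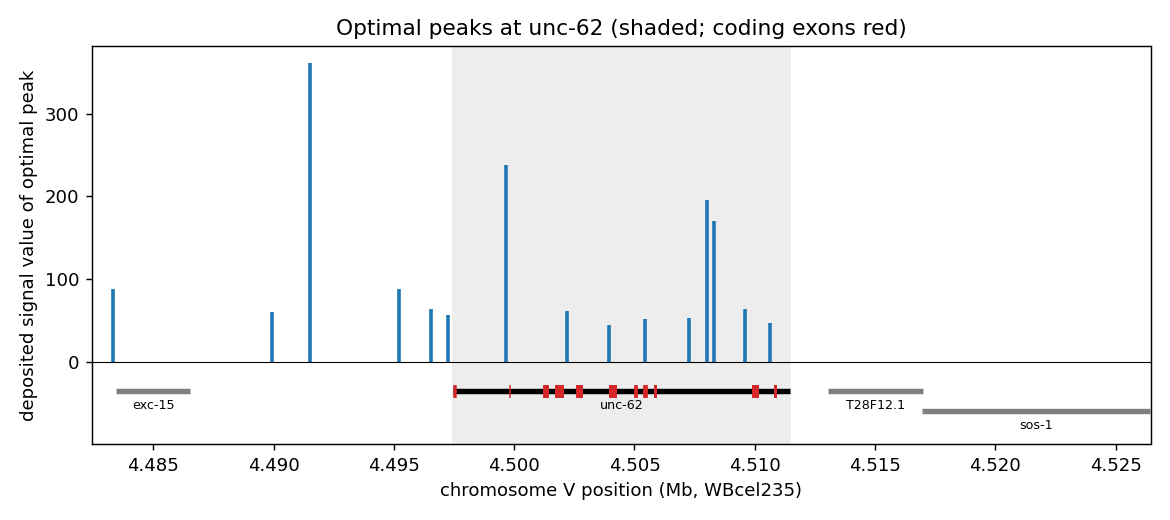
Optimal peaks round unc-62 on chromosome V (x axis, Mb, WBcel235); each blue line stands at a summit with the deposited signal value of the pooled call as its height (y axis), unc-62 is shaded with its coding exons in red, and neighbouring genes are grey. The highest peak, signal 361, stands upstream of the gene.

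Summits of UNC-62 peaks were enriched for TGACAG, the core site of Meis-type homeodomain proteins, and for GATA-type and GA-rich sequence. TGACAG occurred within 50 bp of 13.1% of optimal summits and in 3.53% of flanks, a ratio of 3.71 (permutation p = 0.0001, the smallest possible), rank 14 of 2080 hexamers. By library the ratio was 1.67, 1.76, 3.70, 3.82, 1.43 and 1.24, a mean of 2.27 ± 1.17 (SD, n = 6), above 1 in 6 of 6. The hexamer rank of TGACAG was 214, 221, 7, 8, 52 and 262 in replicates 1 to 6. The GATA pattern WGATAR occurred at 42.9% of summits against 21.6% of flanks, a ratio of 1.99 (permutation p = 0.0001). Its library ratios were 1.05, 1.06, 2.36, 2.20, 1.05 and 1.02, and it did not pass in replicates 1, 2, 5 and 6 (permutation p from 0.119 to 0.295). GAGAG gave 2.48, with library ratios of 1.99, 2.22, 2.23, 2.30, 1.22 and 1.25. The Hox-Pbx pattern TGATTNAT gave 1.58 (permutation p = 0.0002), with library ratios of 1.39, 1.23, 1.58, 1.20, 1.11 and 1.15, and did not pass in replicates 2, 4, 5 and 6 (permutation p from 0.0622 to 0.216). The composite TGAKTGACAG was at 14 summits, 0.507%, a ratio of 28 (permutation p = 0.0003) that rests on 0.0181% of flanks, a single flank window. It did not pass in replicates 1, 2, 5 and 6 (permutation p from 0.0604 to 0.504).

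Other hexamers ranked above TGACAG. ACGCAG was first, at 10.7% of summits against 1.74% of flanks, and CTTATC, a GATA-type site, had rank 3, at 19.3% against 3.78%. ACGCAG ratios were 3.58, 4.07, 4.90, 4.70, 1.60 and 1.66 in replicates 1 to 6, and CTTATC ratios 1.30, 1.47, 6.24, 5.61, 1.38 and 1.43. These hexamers were chosen by their ranks, so no p is given for them.

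**Figure D4:**
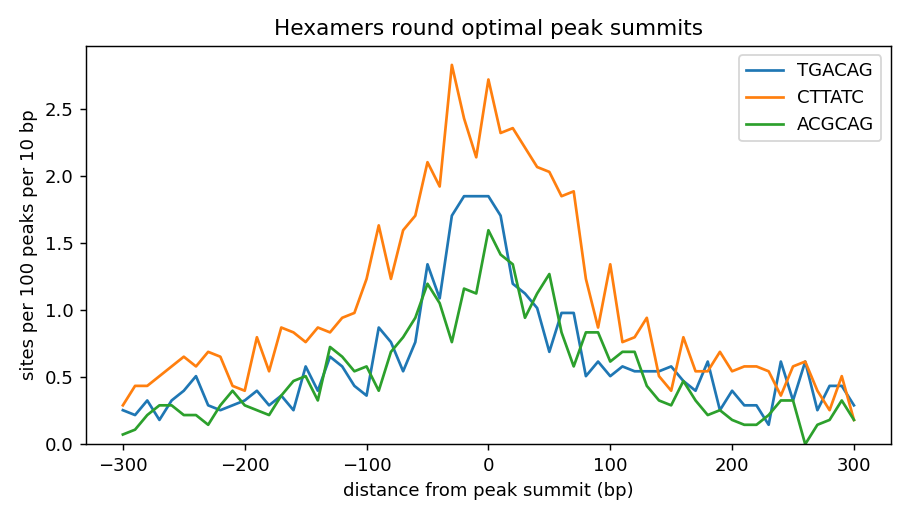
Sites of TGACAG, CTTATC and ACGCAG per 100 optimal peaks in each 10 bp bin (y axis) by distance from the summit in bp (x axis). All of them peak near the summit, where TGACAG reaches 1.85 per 100 peaks against 0.254 at the left edge.

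**Figure D5:**
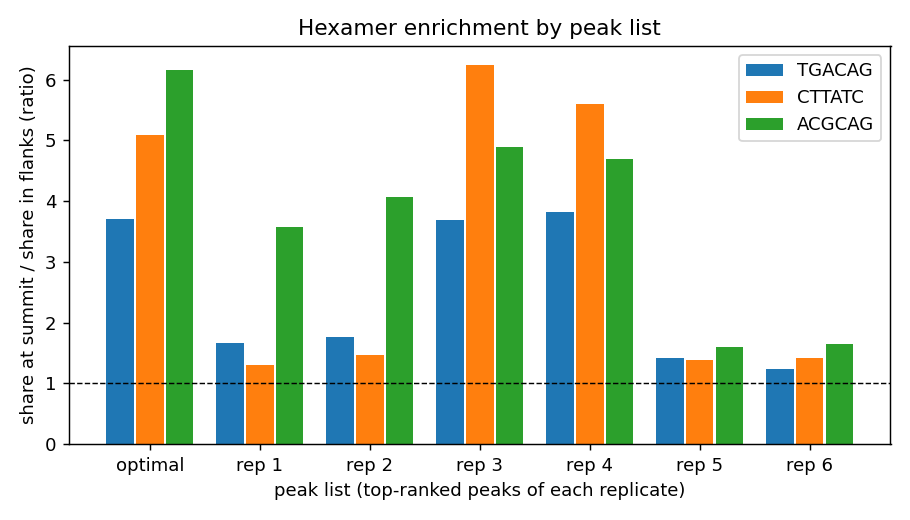
Ratio of the share of windows with each hexamer at summits to that in flanks (y axis, bars from 0, dashed line at 1) for the optimal list and the top-ranked peaks of each replicate (x axis). CTTATC stands at 6.24 and 5.61 in replicates 3 and 4 and at 1.30 to 1.47 in the other libraries.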

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

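The patterns weighed here were seen first, and the tests on GAGAG sites and on the worm source label were chosen only after the values behind them were seen. Of 32 values per library tested for a library standing apart, 3 did, where chance gives about 1.6. The ratio of TGAKTGACAG reached 21 in replicate 3, on 21 windows with the pattern and 0.0362% of flanks. No Hox gene was bound in replicate 5, which gave 0, while each other library gave 2. Replicate 3 had 2 peaks within 15 kb of unc-119, the other libraries 8 to 10. The lists of replicates 3 and 4 each held 27 mitochondrial peaks and the others 0; these peaks entered no comparison.

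Vitellogenin promoters and TGACAG sites were prominent in replicates 3 and 4 and less so in replicates 1 and 2, where no vitellogenin was bound and TGACAG, at ratios of 1.67 and 1.76, was still above its flanks. An even loss of all sites in replicates 1 and 2 would spare no motif. Of 1585 peaks in the top-ranked lists of both replicates 3 and 4, 462 with GAGAG only and 186 with TGACAG only were compared. Those with GAGAG were found again in replicates 1 and 2 more often, by 29.5 percentage points at matched signal (permutation p = 0.005, the smallest possible after multiplying by the 10 pairs of planned motifs). This argues against an even loss. GAGAG was taken for this test after its library ratios were seen, and the factor of 10 covers only the choice of pair. A like difference of 32.4 points for ACGCAG decides nothing, since that hexamer was picked because it ranked 1 in both, and lower enrichment that spares sites called without UNC-62 stays open, as no input track was analysed here. For the worm source label, the lowest TGACAG ratio of replicates 3 and 4 exceeded the highest of replicates 5 and 6 by 2.27. These libraries share that label. Weak enrichment in replicates 5 and 6, which the test described next leaves open, could hide an effect of the label there. Such uneven lower enrichment and the label cannot be told apart for this pattern, and no biological explanation was tested, since the design has 1 condition.

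Top-ranked peaks of replicates 5 and 6 seldom matched the optimal list. If weak enrichment left mostly background in those lists, matches should gather at the top. Of their 200 highest peaks 61% and 57% matched, against 9.03% and 6.02% of those ranked below the first 1000, ratios of 6.76 and 9.47. This was predicted for weak enrichment in those libraries. Replicates 1 and 2 gave ratios close to that of replicate 5, so the test does not single out replicates 5 and 6. The pooled alignments behind the optimal list also left out replicates 5 and 6, which alone can lower their match. Replicates 1 to 4 gave ratios of 6.23, 6.01, 1.96 and 1.94, the last 2 held down because 99% and 98% of their 200 highest peaks matched and 50.5% of the lower ranks did in each. No biological explanation was tested.

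Signal at unc-62 was high in every library. Extra copies of the locus on the transgene predict many peaks over the whole region, and the number within 15 kb was at or above percentile 99.9 of 2000 other genes in each library. That is consistent with extra copies. Clustered binding of UNC-62 at its own gene predicts the same count and stays open. At unc-119, the marker gene, the percentiles ran from 4.05 to 41.5, so no such excess was seen there. How much unc-119 sequence the transgene carries was not examined, so this decides nothing about extra copies.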

How the results depend on the processing

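Of 47 alternative values for 8 results, 38 kept their direction and side of the threshold or moved by less than their spread. Some of the 38 could hardly fail, so the count does not measure how firm the results are. The 2 alternatives of the peak number were counted as kept without a bound. Another 11 were mean overlaps of pairs, kept when within 12.8 points of 15.1%. For the number of lists, values from 3 to 6 counted as kept. The label comparison is left out of this count, and values for replicates 1 to 4 alone or without 1 library were chosen after seeing the data. Ratios of single lists are left out too. Under alternatives the intestinal ratio passed in 5 and not in 6, and the TALE ratio passed in 6 and not in 5. The vitellogenin ratio passed in 7, did not pass in 1 and fell to 0 in 3. The share of optimal peaks matched in every library, 2.10%, was 3.77% with an overlap of 1 bp, 2.83% with the top 5522 peaks, 7.32% with whole lists, 3.48% in replicates 3 to 6 and 8.48% in replicates 1 to 4. The last 4 follow from longer lists or fewer libraries. The number of lists bound more often than other genes, 4, was 9 with the nearest TSS only. That setting also counted the 1420 optimal peaks outside promoters. The number was 2, 2 and 1 with the peaks of replicates 1, 5 and 6, and the cause of these lower numbers was not tested. The vitellogenin ratio of 11.2 fell to 0 in replicates 1, 2 and 6, because no vitellogenin promoter held a top-ranked summit there; the cause was not tested. The mean overlap of pairs, 15.1%, was 11.2% to 18.7% with each library left out in turn and 25.3% among replicates 1 to 4 alone. Ribosomal protein genes passed under each alternative, with ratios from 2.25 to 7.12. TGACAG kept a ratio above 1 and passed under each alternative, from 1.24 in replicate 6 to 4.51 with 25 bp each side. The difference between worm-source labels, 4.23 points, could not pass under any alternative, as its smallest exact p is 0.0667; it ran from 3.70 to 6.36 points with 6 libraries, from 0.0513 to 9.18 with each library left out in turn, and was 19.7 among replicates 1 to 4, where 3 splits allow no exact p below 0.333. Of 48 named list genes, 20 had no promoter peak among the 1380 peaks of highest signal. Unknown depth limits all comparisons of list content between libraries.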

Other observations

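All tests in this part were chosen after seeing the data. Among 170 gene families defined by a shared name prefix, 6 were bound more often than other genes and 2 less often (Fisher's exact test, Benjamini-Hochberg). Galectin genes (lec) were bound in 6 of 12 cases (exact test, adjusted p = 0.00369), including lec-8, lec-10 and lec-6, and UDP-glucuronosyltransferase genes (ugt) in 13 of 67 (exact test, adjusted p = 0.0262), led by ugt-50 and by ugt-49, whose peak had signal 234. The libraries bound 1, 2, 15, 16, 4 and 2 ugt genes in replicates 1 to 6. Genes of the lin class gave 12 of 45 (exact test, adjusted p = 0.00354). Some of these genes share a peak with a neighbour: the lin-54 summit is also that of rpl-12, and the lin-35 summit that of vps-51. The vps genes gave 9 of 31 (exact test, adjusted p = 0.00866), and the rps and rpl families were the other 2 above. The chemoreceptor families str, with 1 of 193, and srw, with 0 of 109, were bound less often (exact test, adjusted p = 0.000636 and 0.00866).

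Some optimal summits lay within 250 bp of snoRNA or tRNA genes. There were 61 at snoRNA genes (2.21% of summits), 10.7 times the random number, and 70 at tRNA genes (2.54%), or 6.81 times (permutation p = 0.0001 for each, the smallest possible). The random positions were not matched on annotation, while 57.4% of optimal summits were intergenic against 35.3% of random positions. Part of the excess may come from that. With no control track analysed, signal at these genes without UNC-62 was not set apart. The snoRNA excess was 5.77, 5.63, 7.63, 10.3, 4.39 and 3.81 times in replicates 1 to 6, and the tRNA excess 4.41, 5.52, 5.29, 6.22, 2.04 and 1.84 times. At miRNA genes 11 summits gave 2.70 times the random number (permutation p = 0.0029), and replicates 2 and 5 did not pass (permutation p = 0.36 and 0.0501).

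The leading hexamers marked partly different peaks. ACGCAG was found at 5.45% of peaks with CTTATC and 11.98% of peaks without it (Fisher's exact test, adjusted p = 3.87e-05). Peaks with ACGCAG lay in promoters in 60.1% of cases against 47.2% of other peaks (exact test, adjusted p = 0.000189), and on X in 19.3% against 26.6% (adjusted p = 0.0159). CTTATC was at 24.9% of TGACAG peaks and 18.4% of others (exact test, adjusted p = 0.0156). None of 532 CTTATC peaks stood in the promoter of a ribosomal protein gene, against 1.30% of other peaks (exact test, adjusted p = 0.0147). Of 362 TGACAG peaks 1 stood in such a promoter, 0.276% against 1.17% of other peaks (exact test, adjusted p = 0.231). Of 296 ACGCAG peaks 5 did, 1.69% against 0.974% (exact test, adjusted p = 0.268). Neither of these passed.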
